A study of Rattus norvegicus with 16 samples.

How the data were processed

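RNA sequencing was done on the hypothalamus of 21-day-old female Wistar rats, in tissue the labels call MBH-PoA. The labels' protocols state exposure to a mixture of endocrine disrupting chemicals (EDC) or to vehicle, through food given along the maternal lineage from 2 weeks before gestation to the end of lactation. The F1 rats were exposed in utero and the F3 rats ancestrally. Each combination of generation and treatment has 4 libraries, 16 in all. Groups were taken from the source description of each sample, because the titles of all 8 EDC samples read Control whereas their treatment fields name the EDC mixture. How animals were allocated, whether any of them were littermates and when the tissue was taken are not given in the sources used here.

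Per the labels' protocols, the libraries were made with standard Illumina protocols and sequenced on an Illumina HiSeq instrument with single reads of 100 cycles, 4 samples per lane. The deposited file names carry one lane number for the F1 libraries and another for the F3 libraries, so generation and sequencing run cannot be separated. One lane number for the 8 libraries of a generation conflicts with the stated 4 samples per lane, so which libraries shared a lane is not clear. The submitters' processing notes name Trimmomatic 0.33, TopHat2 2.1 and the rat genome build rn6. The deposited files hold read counts per gene in the layout that the aligner STAR writes, whose version is not given in the sources used here. Each file lists 32883 Ensembl rat gene IDs with 3 columns of whole-number counts (unstranded and the 2 strands), after 4 summary lines for unmapped, multimapping, no-feature and ambiguous reads.

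The fourth column was used by a rule fixed before the data were examined, which asks that it hold at least 5 times as many gene counts as the other stranded column in every library. The lowest ratio was 52.5. The summary lines stayed out of library sizes and tests. Multimapping reads took 15.7% to 51.6% of the reads of a library, no-feature reads 17.7% to 24.4% and unmapped reads 3.63% to 9.45%. Gene counts per library ran from 5655354 to 35981898. No pair of replicates held identical counts.

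Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust dispersion on a model of 4 group means over all 16 libraries. The filterByExpr step (count minimum 10) left 15366 genes. The threshold was a Benjamini-Hochberg adjusted p of 0.05, two-sided. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values were computed here from the deposited counts with TMM factors. Principal components and correlations between libraries used log2 CPM (prior count 2) of the tested genes. The comparisons were F1 EDC against F1 control, F3 EDC against F3 control, the difference between those effects as an interaction contrast, and F3 control against F1 control. Overlaps of calls were tested with Fisher's exact test. Library measures were compared with a two-sided exact permutation test, whose smallest p for 4 against 4 is 0.0286, adjusted over 22 tests.

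The procedure was tested on simulated data with mean levels and gene dispersions taken over all 16 libraries and the sizes of the real libraries. Few genes were changed: 67, 65 and 63 of those tested at 0.5, 1 and 2 on the log2 scale in F1. In F3 the counts were 66, 66 and 65. Recovery with more changed genes was not tested. In the F1 simulation (15163 genes) it recovered 31.3% of genes changed by 0.5 on the log2 scale, 70.8% at 1 and 88.9% at 2, and 3.15% of its calls were false. In the F3 simulation (15173 genes) the shares were 31.8%, 69.7% and 89.2%, with 3.85% false.

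The alternatives were RLE and upper quartile factors, DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, no filter and a filter at a mean log2 CPM of 1, each generation fitted alone, unstranded counts, the replicate number as a block, 1 surrogate variable (sva 3.50.0) and leaving out each library in turn. These choices were made before the data were examined. The share of multimapping reads as a covariate, and a fit without the libraries in which that share was over 40%, were added after seeing the data.

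The deposited files do not pair the IDs with gene names. The gene table at hand (47357 genes, assembly GRCr8) holds no Ensembl ID, so 0 of the 32883 IDs were paired with a symbol. The 42 planned gene lists, the planned named genes, the markers of cell types and the check of the animals' sex from Y-linked genes were therefore left out, as were checks of GC content and gene length. The planned rule for naming genes took those with the smallest p in each direction among genes past the threshold with a mean log2 CPM of at least 0 and a symbol. Without symbols, it was applied to IDs, limited to 2 that rose and 2 that fell in each EDC comparison.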

Results

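Gene expression was measured by RNA sequencing in the hypothalamus of 16 female rats at 21 days of age. The rats descended from mothers that received a mixture of endocrine disrupting chemicals (EDC) or vehicle, and 4 rats were measured in each of the groups F1 control, F1 EDC, F3 control and F3 EDC. F1 rats were exposed in utero, whereas the exposure of F3 rats was ancestral. The design asks how expression differs between exposed and control animals in each generation. Total reads per library ran from 18741016 (F1 control replicate 4) to 110598350 (F1 EDC replicate 4). The counts assigned to genes in replicates 1 to 4 were 14175856, 19249536, 13967526 and 5655354 in F1 control, and 13837319, 13150495, 9859178 and 35981898 in F1 EDC. They were 28768727, 22125141, 24570686 and 10987632 in F3 control, and 30850837, 20823299, 24401433 and 10285902 in F3 EDC. The exact permutation tests found no difference in gene counts between EDC and control past the threshold in F1 (two-sided p = 0.686, adjusted 0.943, n = 4) or in F3 (two-sided p = 1, n = 4).

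The share of reads that mapped to several places differed widely between libraries, from 15.7% to 51.6%. It averaged 46.2% ± 4.11 in F1 EDC and 35.3% ± 10.6 in F1 control (SD, n = 4; two-sided exact permutation p = 0.0571, adjusted 0.180). In F3 it was 24.7% ± 13.6 in EDC and 30.8% ± 11.1 in control (SD, n = 4; two-sided exact permutation p = 0.514, adjusted 0.808). Unmapped reads were 4.24% ± 0.244 in F1 EDC and 6.91% ± 1.85 in F1 control (SD, n = 4; two-sided exact permutation p = 0.0286, the smallest this design can give, adjusted 0.126). Genes detected numbered 17762 ± 331 in F1 EDC and 16941 ± 381 in F1 control (SD, n = 4; two-sided exact permutation p = 0.0286, adjusted 0.126).

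The 4 F1 EDC libraries lay apart from the other 12. The first principal component held 46.2% of the variance of log2 CPM over 15366 genes. F1 EDC libraries scored 86.7 ± 1.45 on it (SD, n = 4), and the other 12 libraries lay between -37.9 and -11.5. The second component (10.6% of the variance) separated F1 control, at 38.6 ± 10.4, from F3 control, at -23.8 ± 5.05, and F3 EDC, at -11.96 ± 5.47 (SD, n = 4 each). The F3 EDC scores on it were higher than those of F3 control in every library (two-sided exact permutation p = 0.0286, adjusted 0.126 over 22 tests, n = 4). The biological coefficient of variation within a group was 20.9% in F1 control, 15.5% in F1 EDC, 17.1% in F3 control and 15.3% in F3 EDC.

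**Figure D1:**
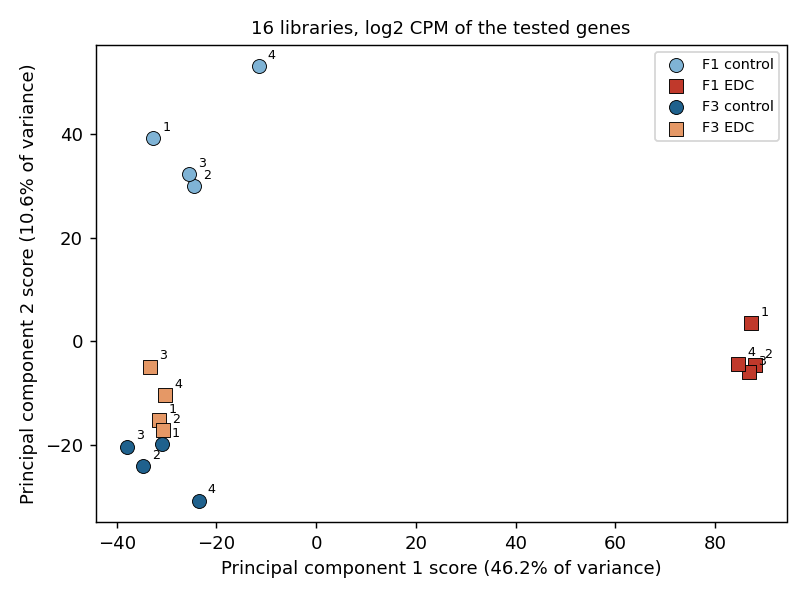
Scores of the 16 libraries on the first and second principal components of log2 CPM (axes in score units), with points numbered by replicate. The 4 F1 EDC libraries lie at 84.7 to 88.0 on the first component and the other 12 between -37.9 and -11.5.

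The F1 comparison asks how the exposed rats differed from controls. The labels call the exposure in utero, but the stated period runs to the end of lactation, and the contrast does not separate the parts of that period. Of the 15366 genes tested, 8057 (52.4%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3907 higher and 4150 lower in EDC. Upper quartile factors gave 4266 higher and 3843 lower, RLE factors 4069 and 3994, and DESeq2 4195 and 4072, so which direction held more genes depended on the scaling. Among the 8057 genes, 1262 were over 2-fold higher and 1393 over 2-fold lower, and 282 were over 4-fold higher and 459 over 4-fold lower. The median absolute log2 fold change was 0.71 among the called genes and 0.44 over all tested genes. The called genes held 68.3% of the gene counts. For 6765 genes (44.0%, where chance gives 2.86% for a single gene) the 4 EDC values did not overlap the 4 control values, and 6515 of these were among the called genes. Leaving out any 1 of the 16 libraries gave 7556 to 8141 genes.

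The deposited files do not pair gene IDs with names, so 2 IDs that rose and 2 that fell are given, those with the smallest p. ENSRNOG00000017445 rose from 184 ± 10.3 CPM in F1 control to 2441 ± 118 CPM in F1 EDC (SD, n = 4), a log2 fold change of 3.73 (SE 0.07; edgeR adjusted p = 1.54e-20). In F3 it was at 155 ± 6.42 CPM in control and 128 ± 10.9 CPM in EDC, a log2 fold change of -0.27 (SE 0.07; edgeR adjusted p = 0.0277), opposite to F1. ENSRNOG00000004781 rose from 150 ± 11.6 to 973 ± 11.7 CPM in F1, a log2 fold change of 2.70 (SE 0.07; edgeR adjusted p = 2.18e-18), and was at 171 ± 8.47 and 160 ± 8.04 CPM in F3 control and F3 EDC. ENSRNOG00000016013 was at 279 ± 27.2 CPM in F1 control and 28.3 ± 3.37 CPM in F1 EDC, a log2 fold change of -3.30 (SE 0.09; edgeR adjusted p = 4.60e-18), against 262 ± 15.2 and 256 ± 4.51 CPM in F3 control and F3 EDC. ENSRNOG00000037957 was at 63.1 ± 4.31 CPM in F1 control and 8.02 ± 0.980 CPM in F1 EDC, a log2 fold change of -2.96 (SE 0.09; edgeR adjusted p = 8.61e-17), against 66.9 ± 4.36 and 79.8 ± 2.20 CPM in F3 control and F3 EDC. In each of these genes all 4 F1 EDC libraries lay on the same side of all 4 F1 controls. Among them, only ENSRNOG00000017445 passed the threshold in F3.

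The F3 comparison asks whether ancestral exposure left a difference. By the same test, 452 genes (2.94%) passed the threshold, 165 higher and 287 lower in EDC, and 2549 genes had an unadjusted p under 0.05. With upper quartile factors 384 genes passed, 200 higher and 184 lower, and with the filter at a mean log2 CPM of 1 there were 217 higher and 197 lower, so the balance of directions was not settled by these data. Only 3 of the 452 called genes were over 2-fold higher and 11 over 2-fold lower. The median absolute log2 fold change was 0.42 among called genes and 0.16 over all tested genes, and the called genes held 4.90% of the gene counts. DESeq2 called 765 genes in this comparison and limma voom with sample quality weights 1508. Without the 8 libraries in which over 40% of reads were multimapping, a fit added after seeing the data, edgeR called 0 genes. Its smallest adjusted p was 0.0546, and 2240 genes had an unadjusted p under 0.05. It lacked F3 control replicate 1 and F3 EDC replicate 4, which left 3 F3 libraries per group. The multimapping share and the smaller number of libraries are therefore not told apart in it. With all F3 libraries, the EDC and control values did not overlap for 1882 genes (12.2%, where chance gives 2.86% for a single gene), among them 423 of the called genes. Genes vary together between libraries, so the share in a chance split may lie elsewhere, and it was not computed. The count rested on single libraries: it was 34 without F3 EDC replicate 3, 87 without F3 control replicate 2, 199 without F3 control replicate 1, 240 without F3 EDC replicate 1, 258 without F3 EDC replicate 2 and 270 without F3 EDC replicate 4. Over all 16 libraries left out in turn it lay between 34 and 553. Without F3 EDC replicate 3 the 452 genes had a median log2 fold change of 0.38 in the called direction, against 0.42. They were chosen with that library, which favours a kept size.

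**Figure D2:**
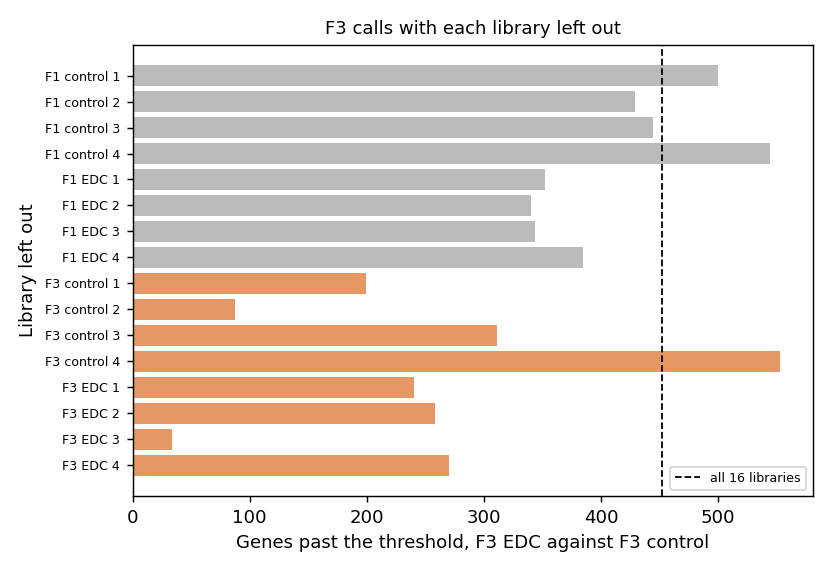
Number of genes past the threshold in F3 EDC against F3 control (horizontal axis) with each of the 16 libraries left out in turn (1 bar each, F3 libraries in orange, F1 libraries in grey). The dashed line marks the 452 genes called with all 16 libraries, and the lowest bar, without F3 EDC replicate 3, is at 34.

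The IDs with the smallest p in F3 had small changes. ENSRNOG00000024186 was at 58.3 ± 3.89 CPM in F3 control and 87.3 ± 5.95 CPM in F3 EDC (SD, n = 4), a log2 fold change of 0.59 (SE 0.07; edgeR adjusted p = 0.000406). Its F1 values were 109.5 ± 3.79 CPM in control and 146 ± 7.15 CPM in EDC. ENSRNOG00000001611 was at 77.9 ± 9.47 and 112 ± 4.76 CPM in F3 control and F3 EDC, a log2 fold change of 0.52 (SE 0.08; edgeR adjusted p = 0.00271), and at 115 ± 5.33 and 143 ± 4.82 CPM in F1 control and F1 EDC. ENSRNOG00000025589 was at 97.7 ± 6.89 and 59.3 ± 8.18 CPM in F3 control and F3 EDC, a log2 fold change of -0.72 (SE 0.09; edgeR adjusted p = 0.000445), and at 47.1 ± 2.68 and 76.1 ± 5.75 CPM in F1 control and F1 EDC. ENSRNOG00000031778 was at 93.0 ± 11.9 and 57.8 ± 7.77 CPM in F3 control and F3 EDC, a log2 fold change of -0.69 (SE 0.10; edgeR adjusted p = 0.00193), and at 42.1 ± 3.87 and 27.5 ± 1.48 CPM in F1 control and F1 EDC. The 4 F3 EDC values of each of these genes lay on one side of the 4 F3 controls.

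**Figure D3:**
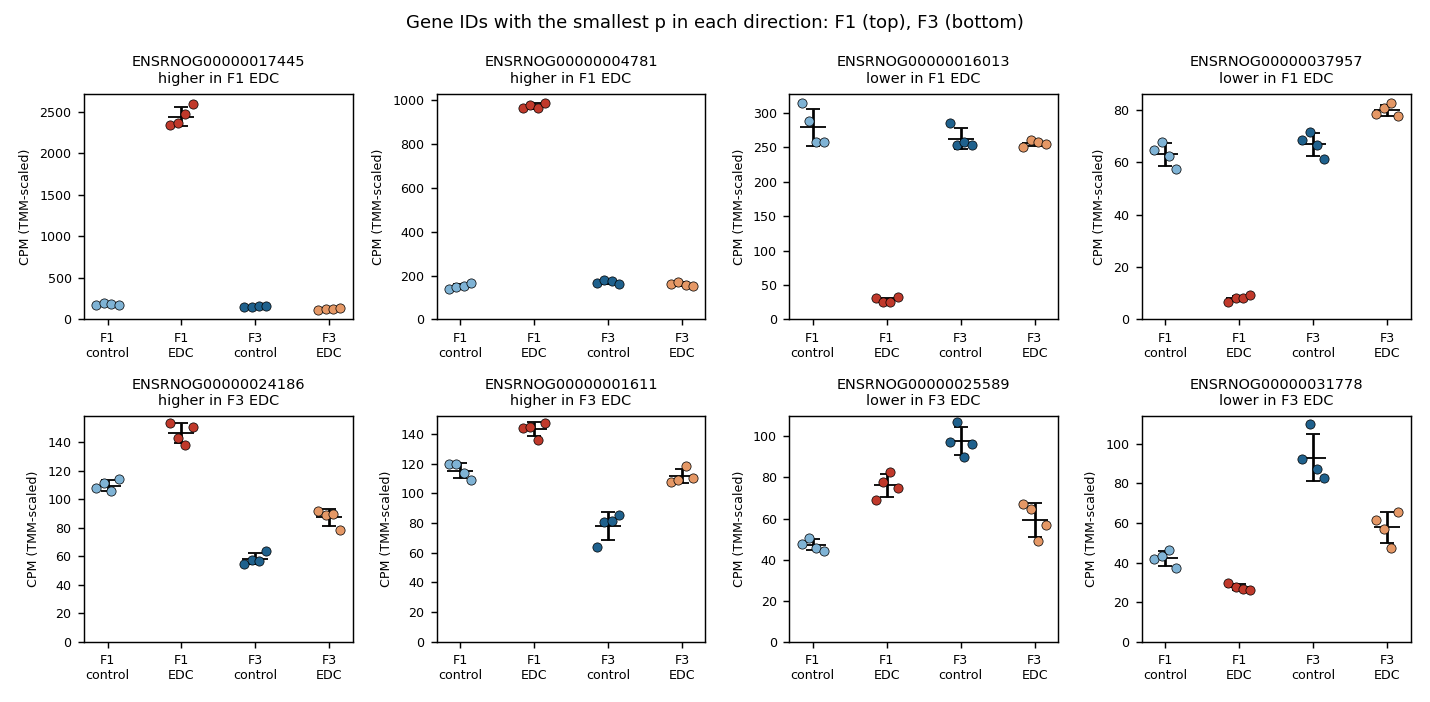
CPM with TMM scaling (vertical axes, from 0) of the 8 gene IDs, with 1 point per library, 4 per group, and bars at the mean ± SD. The upper panels show the IDs chosen in F1, where the F1 EDC libraries lie apart from the other 12, and the lower panels show those chosen in F3.

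The contrasts of EDC against control in the 2 generations were compared directly. The interaction contrast called 6699 genes in edgeR's quasi-likelihood test, 3349 with a higher and 3350 with a lower log2 fold change in F3 than in F1. Across the 15366 genes, which are not independent replicates, the log2 fold changes of F1 and F3 had a Pearson r of -0.0730 and a Spearman rho of -0.0977. Among 100 drawn relabellings of EDC and control within the generations, the real one included, 49 gave an absolute r as large. Called in both generations with the same direction were 95 genes, 45 higher, where independent lists would share 42.0 (one-sided Fisher's exact p = 0.320, adjusted 0.426), and 50 lower, where they would share 77.5 (one-sided Fisher's exact p = 0.99996, adjusted 0.99996). The count of 95 was 171 with DESeq2 and 364 with voom. Without single libraries it was 13 (F3 EDC replicate 3), 24 (F3 control replicate 2), 43 (F3 control replicate 1), 48, 57 and 55 (F3 EDC replicates 1, 2 and 4) and 162 (F3 control replicate 4). Called in opposite directions were 236 genes. Of these, 159 were higher in F1 and lower in F3, against 73.0 from independent lists (one-sided Fisher's exact p = 1.12e-27, adjusted 4.47e-27), and 77 were lower in F1 and higher in F3, against 44.6 (one-sided Fisher's exact p = 4.47e-08, adjusted 8.94e-08). Fisher's test treats genes as independent, and relabelling the libraries, which does not, gave a same-sign share as far from 50% in 11 of 35 splits of the F1 libraries. The directions also rest on the F1 labels: the counts of 95 and 236 would swap if F1 EDC and F1 control had been exchanged.

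**Figure D4:**
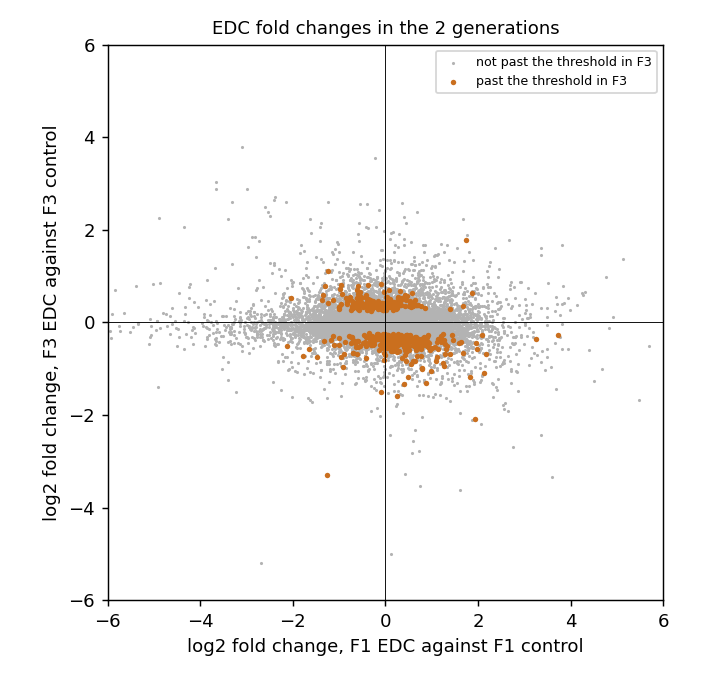
Log2 fold change of F3 EDC against F3 control (vertical axis) and of F1 EDC against F1 control (horizontal axis), 1 point per tested gene, with the 452 genes called in F3 in orange. The axes end at 6 on the log2 scale and leave out 45 genes, and r over all genes is -0.0730.

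F3 control differed from F1 control in 4233 genes by edgeR's quasi-likelihood test, 2250 higher and 1983 lower in F3, of which 472 were over 2-fold higher and 105 over 2-fold lower. With upper quartile factors 2042 were higher and 2474 lower, and with no filter on low counts 2330 and 1513, so this balance depended on the processing too. The F1 and F3 libraries carry different lane numbers, and no number is shared by both generations, so generation and sequencing run cannot be told apart in this contrast. Fitted in the same model, F1 EDC differed from F3 control in 8443 genes and from F3 EDC in 8216, and F1 control differed from F3 EDC in 2483.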

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

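Of the tests below, those of multimapping and unmapped reads, genes detected, exchanged labels, admixture, dissection, F3 EDC replicate 3 and the opposite directions were chosen only after the result was seen. The others were set before the value they measure was known.

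The difference between EDC and control libraries was not the same in both generations. By the interaction contrast in edgeR, 6699 genes passed the threshold, and 1 of 100 relabellings, the real one, gave as many. The highest of the others gave 6107, and it was among the 2 of 99 others that kept the F1 groups intact (the lower of those gave 5515), whereas relabellings that broke the F1 groups gave at most 0. The count therefore follows the grouping of the F1 libraries. Among the IDs named, the log2 fold change in F3 minus that in F1 was -4.004 for ENSRNOG00000017445, -2.80 for ENSRNOG00000004781, 3.26 for ENSRNOG00000016013, 3.21 for ENSRNOG00000037957 and -1.40 for ENSRNOG00000025589, each past the threshold. It did not pass for ENSRNOG00000024186, at 0.17 (edgeR adjusted p = 0.181), ENSRNOG00000001611, at 0.21 (edgeR adjusted p = 0.131), and ENSRNOG00000031778, at -0.07 (edgeR adjusted p = 0.736), which changed in the same direction in both generations.

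The pattern behind it is the distance of the 4 F1 EDC libraries from all 12 others. Their values lay above those of all 12 in 2380 genes and below in 2256, and at least 4-fold apart in 31 and 136 of these. For the other groups such counts ran from 24 to 519, with 0 genes 4-fold apart. Of the 35 splits of the F1 libraries, 1, the real one, gave 8057 genes or more, and the highest other gave 7. The real split thus called far more genes than any other. A share of 1 in 35 is the smallest this test can give, and it was not adjusted over the comparisons. It also takes the rats as independent, which unknown litters leave open.

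The tables argue against several technical explanations. If the share of multimapping reads set the pattern, libraries of other groups with a share in the F1 EDC range would lie with them. The 3 such libraries (43.2% to 44.4%) scored at most -25.5 on the first principal component, where the lowest F1 EDC library scored 84.7. The same test went against the share of unmapped reads, where 2 F3 libraries in the F1 EDC range scored at most -30.7. It went against the number of genes detected too, where 2 F3 libraries scored at most -23.5. No F1 control lay in the F1 EDC range of either measure. Within F1 both measures therefore go with treatment, and these 2 tests rest on F3 libraries alone. If the labels of some F1 EDC libraries, but not all 4, had been exchanged with libraries of other groups, another library would resemble F1 EDC. The highest correlation of any other library with an F1 EDC library was 0.917, below the lowest among F1 EDC libraries, 0.972. If the whole F1 EDC group had been exchanged with an F3 group after library preparation, it would share the F3 percentage of counts on the other strand. That was at most 1.64% in F1 EDC and 1.62% in F1 control, and at least 1.70% in the 8 F3 libraries. The gap is narrow, close to the SD of 0.0553 among the F3 libraries. What sets this percentage was not tested, so it argues only weakly against that exchange. A last test took tissue of another kind as less than 50% of the F1 EDC samples, added to tissue made up as in the controls. No gene would then fall below 50% of its control level. Yet 577 of the 9650 genes at 10 CPM or more in F1 control (5.98%) lay below that level by more than 2 SE, and with RLE factors 564 did. This goes against such an added tissue only, since a sample lacking part of the control tissue could lose genes confined to that part.

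What stays open is whether exposure, litter, or the dissection or preparation of these 4 libraries together, made the difference. The median absolute log2 fold change was 0.44 (0.441) in F1 EDC against F1 control, and 0.271 in F3 control against F1 control, a contrast that holds a sequencing run as well as a generation. The difference arose among libraries that carry one lane number for both treatments, though the stated 4 samples per lane leaves open which of the 8 F1 libraries shared a lane. No batch of dissection or library preparation is given, so such handling and exposure cannot be told apart here. Whether rats of a group were littermates is not given either, so litter and exposure cannot be told apart. An exchange of the labels of the whole F1 EDC group with F1 control, or with an F3 group before library preparation, stays open too. It would leave the lowest correlation among these 4 libraries at 0.972 and all others as they are, and the titles of all 8 EDC samples read Control. An exchange with F1 control would turn the direction of every F1 fold change. The 95 genes called in the same direction and the 236 called in opposite directions would then swap. The 143 of 452 F3 calls with the same sign in F1 would become those with the opposite sign. The sign of r between the generations would turn as well. A different piece of tissue in the F1 EDC samples may also give such values. So may one that lacks part of the control tissue, or a mixed one with more than 50% from elsewhere. Without gene names, no marker of a region or cell type was tested.

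Single libraries stood far from the other 3 of their group in 5 of 76 tests, where chance gives about 1 in 20. F1 EDC replicate 4 had 35981898 gene counts, against 9859178 to 13837319 in the others. F1 control replicate 2 had 21.8% no-feature reads (95% Wilson interval 21.8% to 21.9%, counting error only), against 18.5% to 18.8%. In F3 EDC replicate 4, the 10 most abundant genes took 27.3% of gene counts (95% Wilson interval 27.3% to 27.3%, counting error only), against 17.3% to 18.2%. F1 EDC replicate 1 scored 3.44 on the second principal component, against -5.93 to -4.33. F3 control replicate 1 had 285 CPM of ENSRNOG00000016013, against 253 to 258.

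In F3, 1 of 35 splits, the real one, gave 452 genes or more, and the highest other gave 3. That share is again the smallest this test can give and was not adjusted. It takes the rats as independent, which unknown litters leave open. For F3 control against F1 control, 1 of 35 splits gave the 4233 genes, and the highest other gave 84. With the multimapping share as a covariate, 357 of all tested genes passed the threshold, 326 of them among the 452. Adding the share to the model thus did not remove most of the F3 calls. The median log2 fold change of all 452 in the called direction went from 0.42 to 0.41. These genes were chosen without the covariate on the same libraries, which favours a kept size. Without the 8 libraries over 40% multimapping, 0 of the 451 genes fitted stayed past the threshold in edgeR (765 genes passed with DESeq2 and 1508 with limma voom on all libraries). In that fit 2240 of all tested genes had an unadjusted p under 0.05, and the median log2 fold change of the 451 was 0.41 (median SE 0.0990 against 0.0947, with 5 residual degrees of freedom against 12). Whether F3 EDC replicate 3 alone made most of the F3 calls stays open. Without it 34 genes passed, 33 of them among the 452, and 2 of the 35 splits of the other 7 F3 libraries gave as many. The highest other gave 37, with F3 control replicate 4 placed among the EDC libraries, so chance is not excluded for what remains. Without F3 EDC replicate 3, 1702 of all tested genes had an unadjusted p under 0.05, against 2549 with all libraries. All 452 genes kept their sign in that fit, with a median log2 fold change of 0.38 (median SE 0.102 against 0.0947). These genes were chosen with that library, which favours a kept direction and size.

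The directions of the F3 calls in F1 were opposite more often than not, with the same sign in 143 of 452 under the F1 labels as given. On log2 CPM means the share was 31.4%, and 11 of the 35 splits of the F1 libraries gave a share as far from 50%, from 24.3% to 75.7%, so chance is not excluded. The same holds for the correlation of the fold changes across genes, -0.0730, where 49 of 100 relabellings gave an absolute value as large and the highest other was 0.201.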

How the results depend on the processing

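The covariate of multimapping share and the fit without libraries over 40% multimapping were chosen after seeing the data; the other alternatives were planned. In all settings run, the F1 count stayed within 7259 to 8267 genes, the difference between generations within 5885 to 6899, F3 control against F1 control within 3321 to 4554, and r between -0.0981 and -0.00750.

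Apart from the fits that left out a single library, the F3 count moved by over 1.5 times in 3 settings. It was 765 with DESeq2, 1508 with limma voom and sample quality weights, and 0 in edgeR without the 8 libraries over 40% multimapping, a fit that holds no F1 EDC library. The shared calls were 171 with DESeq2 and 364 with voom, against 95. The cause was not tested for DESeq2 and voom. In the reduced fit (8 libraries, 5 residual degrees of freedom in place of 12) 2240 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0546. The 451 called genes that it fitted had a median log2 fold change of 0.41 against 0.42 and a median SE of 0.0990 against 0.0947, though they were chosen with all libraries, which favours a kept size. The fit has fewer libraries by construction.

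Leaving out each library in turn gave 34 to 553 F3 genes, 13 to 162 shared calls, 7556 to 8141 F1 genes, 6088 to 6786 for the difference, 3576 to 4291 for the control groups, and an r of -0.0968 to -0.0187. The shared calls were 13 without F3 EDC replicate 3, 24 without F3 control replicate 2, 43 without F3 control replicate 1, 48, 57 and 55 without F3 EDC replicates 1, 2 and 4, and 162 without F3 control replicate 4. The named IDs of F1 kept direction and call in 108 of 108 alternative fits, and those of F3 in 108 of 112, the other 4 being the reduced fit. These IDs had the smallest p in the main fit, which favours a kept call, so they do not stand for the other calls. Without F3 EDC replicate 3, 33 of the 452 F3 calls stayed past the threshold.

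Replicate numbers did not pair the libraries: 0 of 8 same-numbered pairs deviated together at r over 0.1 (-0.108 to 0.0884), and 2 of 8 controls matched best with their own number. With the replicate block, F1 had 7732 genes, F3 304, the difference 6292, the shared calls 67 and r was -0.0446.

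The planned tests of gene lists and the alternatives for them were not run, for lack of gene names. The simulated data took gene dispersions over all 16 libraries, so their spread was not that of F3 alone. At the library sizes and 4 libraries per group of F3, 31.8% of simulated changes of 0.5 on the log2 scale were recovered. Depth was not varied, so its part in this was not tested.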

Other observations

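The test below was set before its value was known, though the pattern itself was noticed in the data.

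As a group, F3 EDC libraries lay nearer to F1 control than F3 control libraries did, though single libraries overlapped. Correlations of log2 CPM with F1 control libraries averaged 0.959 in F3 EDC (0.948 to 0.970) and 0.955 in F3 control (0.944 to 0.964). F1 control differed from F3 EDC in 2483 genes by edgeR and from F3 control in 4233. Of the 452 genes called in F3, 445 (98.5%) had moved from the F3 control level towards that of F1 control. That share is raised by the F3 control libraries, which enter both contrasts, and so is the correlation across genes of F3 EDC minus F3 control with F1 control minus F3 control, 0.482. With different F3 controls in each contrast (6 ways of halving them), the mean correlation was 0.216, from 0.140 to 0.301, and the covariance 0.0478. Of the 70 assignments of the F3 libraries to EDC and control, 1, the real one, gave a mean as high, and the highest other gave 0.164. Shared controls alone are therefore not the whole cause. How far the pattern rests on single libraries was not tested, and without F3 EDC replicate 3 the F3 comparison called 34 genes in place of 452. A candidate explanation is a state of the tissue, or of its handling, that set the F3 controls apart from both other groups, and another is an effect of ancestral exposure along the same axis. No test here separates these. Other relations of the F3 fold changes, to axes of variation within groups and to the share of the most abundant genes, were looked at without a result that is reported.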
